A study of Mus musculus with 4 samples.

How the data were processed

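RNA of sorted mouse bone marrow cells was measured on 4 Affymetrix arrays: 2 of Hdac3-null LSK/Flt3- cells, 1 of wild-type LSK/Flt3- cells and 1 of wild-type LSK/Flt3+ cells. Per the labels' protocols, RNA was extracted with the PerfectPure kit, labelled with biotin and processed by standard Affymetrix methods, and the mice were of the C57BL/6 background. The deposited values are log2 expression per probe set, made by the authors with RMA and affy 1.23, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes, but the deposited array medians were not equal (5.60, 5.30, 5.32 and 5.36), so what scaling the values carry is not settled. The SD over probe sets with a single gene was 1.88 on null replicate 1 against 2.00, 2.00 and 1.96 on the others. Whether a gene stood above background, the genome build and scan dates are not given in the sources used here, and arrays could not be assigned to batches.

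The table held 35556 probe sets, of which the platform's annotation listed 23410. A single gene symbol was given for 21789, several for 1621 and none was listed for 12146. Probe sets with several or no listed symbols were left out of all tests. Of the single-symbol probe sets, 21698 matched a gene by its Entrez number and 0 symbols needed updating. For each of 19938 genes the probe set with the highest mean over the 4 arrays was used; 999 genes had more than 1. No genome coordinates are printed because no build is named for these arrays.

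Before the data were examined, the grouping, the tests, 30 gene lists, the alternatives in the settings and the rule for naming genes were fixed. All 4 arrays entered 1 limma 3.58.1 fit (R 4.3.3) with 3 groups, moderated with a mean-dependent prior. The fit has 1 residual degree of freedom, from the null pair, and 9.01 prior degrees of freedom, so each lone wild-type array is assumed to vary as the null arrays do. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all genes at 0.05. The median fitted SD was 0.27. Both null comparisons use the same null arrays, so their results are not independent. Genes at least 2-fold from a wild-type array on both null arrays were also counted, without a test.

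The 30 lists covered stem cells, blood lineages, other cell types of marrow, cell cycle and DNA replication, repair, stress, chromatin, lipid, circadian, Hox, imprinted, sex-linked, gate marker and neuronal genes. They held 656 genes, of which 602 were measured. Another 15 had only a probe set shared with other genes and 39, Ddx3y among them, were not named by the annotation, and both kinds were not analysed here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, and again with an estimated correlation, which rests on the 1 residual degree of freedom. With the preset value 11 lists passed against wild-type LSK/Flt3- and 12 against wild-type LSK/Flt3+ cells, and with the estimated one 0 passed in either. The estimate leaves camera the 1 residual degree of freedom, so passing was hardly possible for any list. For the macrophage list against wild-type LSK/Flt3+ cells the estimate was -0.06, below the preset value, yet camera's unadjusted p went from 3.29e-40 to 0.0442. Failure in this second run therefore says little about a list, and the preset calls stand without that check. Each list median was also placed among 10000 random lists of the same size, matched over 20 bins of mean expression. The genes of a random list were drawn independently, so a percentile can be too extreme for a list whose genes vary together. The percentiles do not measure the spread between samples. The wild-type arrays were compared without p-values.

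Genes were named by rule: Hdac3, then up to 10 genes each way with the largest mean difference among those past the threshold and at least 2-fold apart on both null arrays, filled where fewer passed with the largest 2-fold differences. Between the wild-type arrays they were the 10 largest differences each way among genes with a mean of at least 6. Up to 4 members of each list were added, those with the largest differences. Predicted genes were passed over. Other genes named were list members past a test or were chosen after their values were seen.

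The fit was tested on simulated data for null against wild-type LSK/Flt3- cells over 19938 genes. Of 50 genes changed by each size, it recovered 2% at a log2 size of 1, 80% at 2, 98% at 3 and 100% at 4, with 5 false calls in all. The simulated variances were drawn from the fitted prior and were equal on all arrays. The simulation therefore does not check whether the lone wild-type arrays vary as the null arrays do. The simulated genes varied independently, without offsets between arrays, and the many planted changes ease the adjusted threshold, so the shares recovered can be too high. Changes of 2-fold are therefore mostly missed by the adjusted p in this design. Larger ones can be missed too: in the deposited data Ccr2 (log2 difference 3.0, limma adjusted p = 0.107) and Dntt (-3.14, 0.149) did not pass.

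Alternatives were the mean of all probe sets of a gene, every probe set on its own, only genes with a mean of at least 6, cyclic loess between arrays, centring each array on its median, a constant prior, a robust prior, only the 3 arrays of a comparison, fold limits of 1.5 and 3, and leaving out each null array. Quantile normalization was added after the data were seen. Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.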

Results

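Gene expression was measured on 4 Affymetrix arrays in mouse bone marrow LSK cells, the lineage-negative fraction positive for Sca-1 and Kit that holds the blood stem cells and the earliest progenitors. Hdac3, a histone deacetylase that works within corepressor complexes, was deleted in blood cells with a Cre recombinase driven by the Vav promoter. The null LSK/Flt3- group had 2 arrays, and wild-type LSK/Flt3- and wild-type LSK/Flt3+ cells had 1 array each. Flt3 is a cytokine receptor that appears on LSK cells as they leave the stem cell state and gain lymphoid potential. Each array held RNA of sorted cells pooled from 5 to 30 mice. Whether the null replicates came from separate mice is not given in the sources used here, so the limma p-values measure only the spread between these samples, which may be technical. The camera p-values at the preset correlation compare the genes of a list with all other genes. They treat genes as the units and do not measure the spread between samples. The number of arrays limits the precision: the median standard error of a difference between null and wild-type cells was 0.34 on the log2 scale. Array medians over all probe sets were 5.60 and 5.30 for null replicates 1 and 2, 5.32 for wild-type LSK/Flt3- and 5.36 for wild-type LSK/Flt3+.

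Hdac3, the targeted gene, had log2 levels of 5.71 and 5.04 on null replicates 1 and 2, against 6.18 in wild-type LSK/Flt3- and 6.33 in wild-type LSK/Flt3+ cells. Its single probe set was lower on both null arrays, by a log2 difference of -0.81 ± 0.38 (SE) from LSK/Flt3- and -0.96 ± 0.38 (SE) from LSK/Flt3+ cells. Neither difference passed the limma test over all genes (adjusted p = 1 for each). Whether the probes lie within the deleted part of the gene is not given in the sources used here, so these values do not check the labels.

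Across 19938 genes, the wild-type arrays were the closest pair, with an SD of the log2 differences of 0.31 and 219 genes at least 2-fold apart. The null replicates were less alike, with an SD of 0.43 and 563 genes at least 2-fold apart, of which 272 were higher on replicate 1 and 291 higher on replicate 2. Null replicate 2 lay closer to wild-type LSK/Flt3- cells (SD 0.35, 298 genes) than to null replicate 1. For null replicate 1 the SD from wild-type LSK/Flt3- cells was 0.43, with 507 genes. Both null arrays lay farther from wild-type LSK/Flt3+ cells, with SDs of 0.48 and 0.39. The median difference of all genes between null replicates 1 and 2 was 0.14 on the log2 scale.

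The first comparison set null against wild-type LSK/Flt3- cells and asked which genes, including those of DNA replication and differentiation named in the study's title, differ with Hdac3 missing in the same sorted fraction. Ms4a3, a membrane protein gene typical of granulocyte-monocyte progenitors, rose from a log2 level of 7.03 to 10.08 and 10.20 (log2 difference 3.11 ± 0.35, SE; adjusted p = 0.0321). Gimap4, which encodes a lymphocyte GTPase, rose from 5.43 to 8.48 and 8.22 (2.92 ± 0.36, SE; adjusted p = 0.0480). Xist, the RNA that coats the inactive X chromosome, rose from 4.23 to 10.84 and 9.67 (6.03 ± 0.48, SE; adjusted p = 0.00362), and BC018473 rose by 4.05 (± 0.37, SE; adjusted p = 0.00648). The Y-linked genes Kdm5d, Eif2s3y and Uty were lower on both null arrays than in wild-type LSK/Flt3- cells, with levels of 8.02 and 7.31 against 8.66 for Kdm5d, 7.33 and 6.08 against 8.05 for Eif2s3y, and 6.42 and 5.68 against 6.94 for Uty.

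These 4 genes were the only ones past the limma test in this comparison, and 0 genes were lower. At an unadjusted p under 0.05, 219 genes were higher and 259 lower. With robust estimation of the spread, limma called 12 higher and 13 lower genes, while after quantile normalization, chosen after the data were seen, it called 0 in either direction. The adjusted p of Xist ranged from 2.04e-05 to 0.0527 over the 9 other settings, and that of Ms4a3 from 0.000827 to 0.181. Gimap4 ranged from 0.00116 to 0.181 and BC018473 from 2.04e-05 to 0.0527. By size alone, 50 genes were at least 2-fold higher and 76 at least 2-fold lower on both null arrays. With null replicate 1 left out, replicate 2 alone gave 133 higher and 165 lower genes, and with replicate 2 left out, replicate 1 alone gave 267 and 240.

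Among the genes at least 2-fold apart on both null arrays but not past the test, Ccr2, a monocyte chemokine receptor, had a log2 difference of 3.0 (adjusted p = 0.107). Fcer1a, a chain of the IgE receptor, was at 2.66 (adjusted p = 0.149), Alas1, the first enzyme of heme synthesis, at 2.23 (adjusted p = 0.329) and Slamf1, a stem cell surface marker, at 2.18 (adjusted p = 0.174). The small nucleolar RNAs Snora73b and Snora73a were at 2.74 and 2.50. On the lower side, Dntt, the polymerase that adds bases at antigen receptor gene junctions, stood at levels of 5.83 and 4.56 against 8.33 (log2 difference -3.14, adjusted p = 0.149). Satb1, a chromatin organiser needed for lymphoid development, stood at 7.38 and 6.96 against 9.46 (-2.29, adjusted p = 0.162). Ctse was at -2.83, Cldn13 at -2.53, the chemokine Ccl3 at -2.51, the metallothionein Mt2 at -2.50, Tspan8 at -2.40, C1qtnf12 at -2.23, Zbtb10 at -2.22 and the red cell membrane gene Rhag at -2.17, with adjusted p from 0.256 for Ccl3 to 1 for Mt2 and Tspan8. On null replicates 1 and 2 apart, Mt2 was at -3.69 and -1.32, Tspan8 at -3.62 and -1.18 and Ctse at -3.83 and -1.82. Robust estimation brought Ccr2, Fcer1a, Alas1, Slamf1, Dntt and Satb1, among others, past the threshold.

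**Figure D1:**
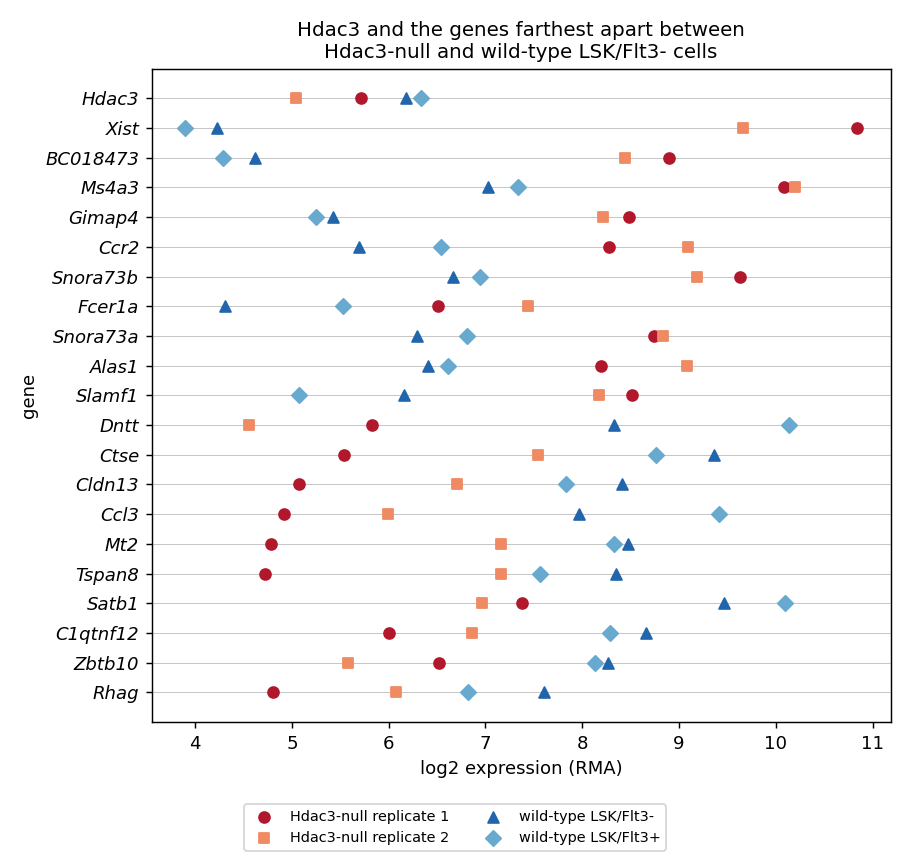
Log2 expression (RMA, x axis) of Hdac3 and 20 other genes (y axis) on each of the 4 arrays, with 1 point per array and no error bars. Xist, BC018473, Ms4a3 and Gimap4, the genes past the limma test between null and wild-type LSK/Flt3- cells, are at least 2-fold higher on both null arrays than on either wild-type array.

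Of the gene lists fixed before the data were examined, the granulocyte-monocyte progenitor list rose in null against wild-type LSK/Flt3- cells, with 20 of 22 members higher and a median log2 difference of 0.73 (camera, adjusted p = 6.13e-15; adjusted p = 0.881 with an estimated correlation). Here and below, failure with an estimated correlation says little, as that test could hardly pass any list with these arrays. The granulocyte-monocyte progenitor median was 0.68 on null replicate 1 and 0.80 on replicate 2. One member, Ms4a3, passed over all genes, and 7 rose when adjusted over the list alone, among them Ccr2, the cytokine receptor chain Csf2rb (1.79) and the granule protease genes Ctsg (1.75) and Prtn3 (1.69). The mast cell, basophil and eosinophil list also rose, with a median of 0.66 and 8 of 12 members higher (adjusted p = 0.00414; adjusted p = 0.881 with an estimated correlation). None of its members passed limma over all genes, 5 were higher at an unadjusted p under 0.05, and Fcer1a and the protease gene Gzmb (1.53) passed adjusted over the list alone. Its median was 1.20 on null replicate 2 and 0.26 on replicate 1, at percentiles 100 and 83.1 of matched random lists.

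Lymphoid priming genes fell as a list, with 11 of 20 members lower, a median of -0.07 and a mean of -0.47 (adjusted p = 7.41e-07; adjusted p = 0.881 with an estimated correlation), but that median lay within the central 95% of matched random lists (percentile 2.97). It was -0.12 on each null array alone, outside that range on replicate 1 (percentile 1.64) and within it on replicate 2 (3.10). None passed limma over all genes, 6 were lower at an unadjusted p under 0.05, and 3 fell when adjusted over the list alone: Dntt, Satb1 and Flt3 (-1.75). Flt3 RNA stood at 7.84 and 7.02 on null replicates 1 and 2, 9.18 in wild-type LSK/Flt3- and 10.07 in wild-type LSK/Flt3+ cells. Whether the null and wild-type LSK/Flt3- sorts held the same mix of cells was not tested. These falls can therefore reflect cell makeup as well as changes within cells. B-lineage genes fell with a median of -0.15 and 10 of 15 members lower, led by the surrogate light chain gene Vpreb1 at -1.34 (adjusted p = 0.00414; adjusted p = 0.881 with an estimated correlation). Their median was 0.12 on null replicate 1 and -0.29 on replicate 2, at percentiles 14.5 and 0.01 of matched random lists. Erythroid genes fell with a median of -0.16 and 12 of 19 members lower, and Rhag passed adjusted over the list alone (adjusted p = 0.000214; adjusted p = 0.881 with an estimated correlation). Their median was -0.35 on null replicate 1 and 0.02 on replicate 2, and Car1, a carbonic anhydrase of red cell precursors, was at 6.44 and 10.92 against 11.81 in wild-type cells.

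Immediate early and heat shock genes fell, with 17 of 23 members lower and a median of -0.49 (adjusted p = 2.37e-11; adjusted p = 0.881 with an estimated correlation). The chaperone gene Hspa1a was at -1.46 and the transcription factor gene Jun at -1.35, and 0 members passed limma over all genes or adjusted over the list alone, with 6 lower at an unadjusted p under 0.05. Interferon response genes fell with a median of -0.26 and 18 of 25 members lower (adjusted p = 4.66e-07; adjusted p = 0.881 with an estimated correlation), with Oasl2 at -1.19 and Bst2 at -1.06, and the median was -0.25 on null replicate 1 and -0.40 on replicate 2. The member that passed adjusted over the list alone, the antiviral membrane protein gene Ifitm1, went the other way, at 1.40. Macrophage and dendritic cell genes (median -0.13, adjusted p = 0.00414) and circadian genes (median -0.19, adjusted p = 0.00558) also fell, both with adjusted p = 0.881 with an estimated correlation. On null replicates 1 and 2 the macrophage median was -0.10 and -0.19 and the circadian one -0.09 and -0.31. With only genes of a mean level of at least 6, the adjusted p was 0.377 for the macrophage list, 0.361 for the circadian list and 0.0573 for the erythroid list.

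DNA replication genes, which encode the origin recognition complex, the MCM helicase and the polymerases, did not pass as a list in null against wild-type LSK/Flt3- cells (median -0.04, 26 of 56 higher and 30 lower, adjusted p = 0.0709). None of the 56 passed limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and the members farthest apart were Rpa3 (-0.71), Cdt1 (0.61), Orc6 (-0.57) and Lig1 (-0.53). On null replicates 1 and 2 apart, Rpa3 was at -1.04 and -0.38, Cdt1 at 0.32 and 0.90 and Orc6 at -0.34 and -0.81. The list median was -0.15 on null replicate 1 and 0.04 on replicate 2. Mitosis genes fell slightly, with 21 of 33 lower and a median of -0.10 (adjusted p = 0.00558; adjusted p = 0.881 with an estimated correlation), and the adjusted p was 0.508 after cyclic loess, 0.351 after quantile normalization and 0.304 with only genes of a mean level of at least 6, and the median lay at percentile 6.36 of random lists. The mitosis median was -0.20 on null replicate 1 and -0.02 on replicate 2 (percentiles 2.78 and 37.4). CDK inhibitor genes fell by the test (adjusted p = 0.00651; adjusted p = 0.881 with an estimated correlation) while their median was 0.02, at percentile 21.3 of random lists, and their mean -0.44. Their median was -0.15 on null replicate 1 and 0.02 on replicate 2 (percentiles 2.43 and 44.5). The members behind the fall were Cdkn1b (-1.69), whose product p27 restrains entry into S phase, and Cdkn2c (-1.53), an inhibitor of CDK4 and CDK6, the only 2 of 6 to pass adjusted over the list alone. With the mean of all its probe sets, Cdkn1b was at -1.06, and its adjusted p over all genes, 0.476 as reported, ranged from 0.158 to 1 over the other settings.

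Among the other lists, the median in null against wild-type LSK/Flt3- cells was 0.07 for nucleotide synthesis genes (adjusted p = 0.552), -0.02 for G1 and S cyclin, E2F and RB family genes (adjusted p = 0.118), 0.01 for DNA repair and checkpoint genes (adjusted p = 0.930), 0.09 for p53 target genes (adjusted p = 0.936) and 0.05 for apoptosis genes (adjusted p = 0.868). It was 0.07 for HDAC genes (adjusted p = 0.634) and 0.01 for corepressor complex genes (adjusted p = 0.584). For the nucleotide synthesis, repair, p53, apoptosis, HDAC, corepressor, endothelial and imprinted lists the median was above 0 while the test pointed down. Camera sets a list against all other genes, and the median difference of all genes was 0.09. A list median near or below that value can therefore go with a test that points down. Stem cell (HSC) genes had a median of -0.06 and a mean of 0.06 (adjusted p = 0.584), with Slamf1 past the test adjusted over the list alone and Mecom, a stem cell transcription factor gene, at -1.32. Megakaryocyte and platelet genes had a median of 0.41 (adjusted p = 0.114), which passed after cyclic loess (adjusted p = 0.0395) and with only genes of a mean level of at least 6 (adjusted p = 0.00636) and lay at percentile 100 of random lists. That median was 0.17 on null replicate 1 and 0.59 on replicate 2, at percentiles 83.9 and 100. Mature neutrophil and monocyte genes had a median of 0.26 (adjusted p = 0.743), at percentile 98.7 of random lists (84.8 on null replicate 1 and 100 on replicate 2), but with only genes of a mean level of at least 6 the list fell, with a median of -0.16 (adjusted p = 0.0171). T and NK cell genes had a median of 0.15 (adjusted p = 0.584). The endothelial and stromal list had a median of 0.07 and a mean of -0.03 (adjusted p = 0.516), with the sialomucin gene Emcn at -1.98. PPARg and lipid droplet genes stood at 0.18 (adjusted p = 0.438), Hox cluster genes at 0.02 (adjusted p = 0.944), imprinted genes at 0.01 (adjusted p = 0.552) and neuronal genes at 0.23 (adjusted p = 0.743). Several of these medians had opposite signs on null replicates 1 and 2. Part of this can be offset, since the median difference of all genes between replicates 1 and 2 was 0.14. Imprinted (0.13 and -0.05), endothelial (0.18 and -0.03) and stem cell genes (0.004 and -0.04) lay below the middle of random lists on both arrays. Their percentiles were 16.9 and 12.9, 36.1 and 17.5, and 23.4 and 18.4. The sides did differ for Hox genes, at 0.21 and -0.15 (percentiles 60.2 and 0.28), and neuronal genes, at 0.35 and -0.03 (90.9 and 14.55). They also differed for nucleotide synthesis genes, at -0.13 and 0.12 (18.8 and 91.6), and apoptosis genes, at 0.11 and -0.07 (52.1 and 12.6). DNA repair genes were at 0.14 and 0.02 (percentiles 98.02 and 53.6). The sex-linked list had a median of -0.94 and a mean of 0.70 (adjusted p = 0.413), and the gate markers a median of 0.32 (adjusted p = 0.584), with medians at percentiles 0.03 and 99.3 of random lists. The sex-linked median was -0.58 on null replicate 1 and -1.31 on replicate 2, and that of the gate markers 0.52 and 0.11 (percentiles 99.7 and 73.8).

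**Figure D2:**
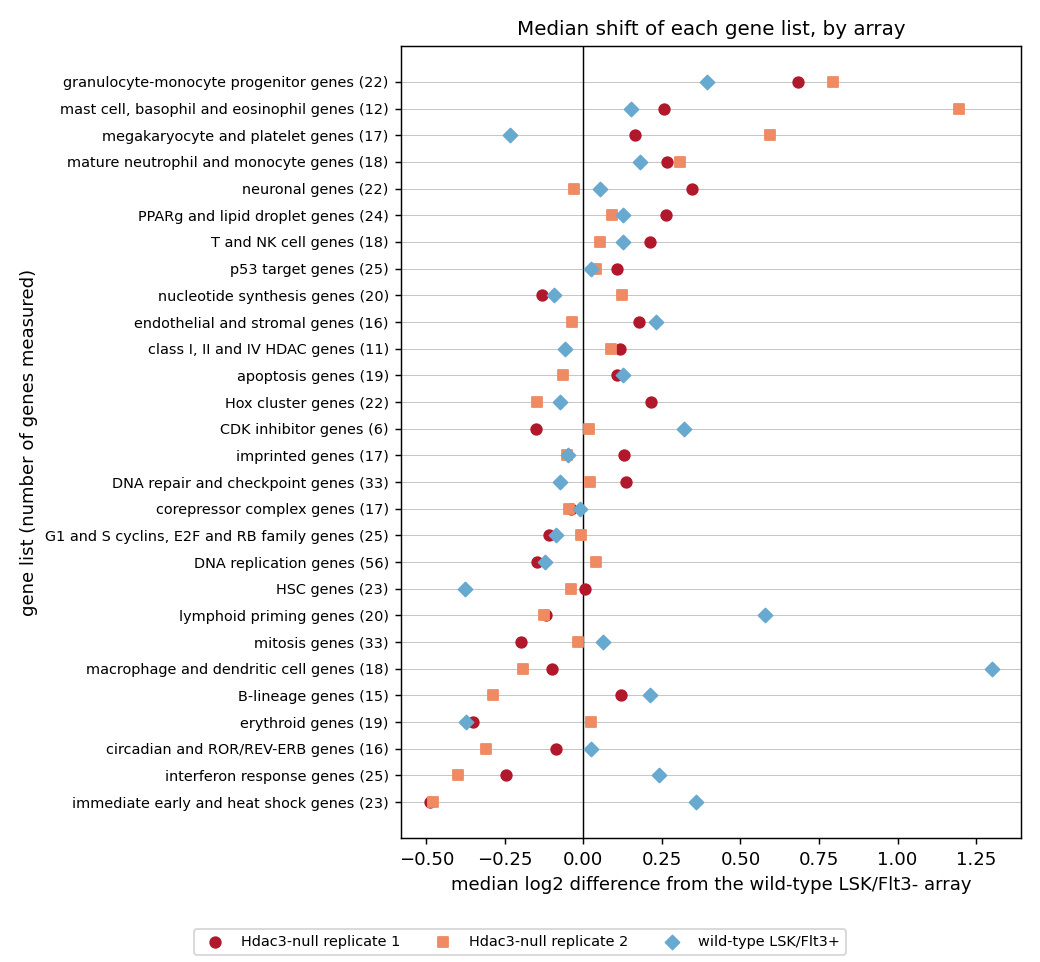
Median log2 difference from the wild-type LSK/Flt3- array (x axis) of each gene list (y axis, with the number of genes measured), for null replicate 1, null replicate 2 and wild-type LSK/Flt3+ cells. Each point is 1 array and has no error bar. The granulocyte-monocyte progenitor list lies at 0.68 and 0.80 on the null arrays, and the macrophage and dendritic cell list at 1.30 in wild-type LSK/Flt3+ cells.

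The second comparison set the same 2 null arrays against wild-type LSK/Flt3+ cells, a different sorted fraction, so that it holds the difference of fraction as well as that of genotype. Dntt fell by 4.95 on the log2 scale (± 0.50, SE; adjusted p = 0.00275), and Satb1 (log2 difference -2.92, adjusted p = 0.00931), Flt3 (-2.64, adjusted p = 0.0317) and the lymphoid cytokine receptor gene Il7r (-2.13, adjusted p = 0.0231) fell as well. Genes typical of macrophages fell, among them the complement gene C1qc (-4.36), the scavenger receptor gene Cd36 (-4.33) and the mannose receptor gene Mrc1 (-4.13), with adjusted p = 0.000514 for each. Against wild-type LSK/Flt3- cells these genes were at -1.07, -0.67 and -0.21, so most of each fall is a difference between the wild-type arrays. On null replicates 1 and 2, C1qc stood at 3.59 and 4.05 and Cd36 at 3.80 and 3.72, below the lower quartiles of all probe sets on those arrays (4.41 and 4.10), as did Il7r, Ms4a7, Retnla and Blnk. Without a background call, the sizes of these differences are uncertain and can be understated, as can those of Xist and Scin, at 3.90 and 3.48 in wild-type LSK/Flt3+ cells (lower quartile 4.18). Slamf1 rose by 3.27 (adjusted p = 0.00506), Scin, which encodes an actin-severing protein, by 3.46 (adjusted p = 0.00188), and Ms4a3 by 2.80 (adjusted p = 0.00931). Xist rose by 6.35 (adjusted p = 0.000514), while the 3 Y-linked genes had a median difference of -0.66.

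In all, limma called 7 higher and 56 lower genes in null against wild-type LSK/Flt3+ cells. The other genes higher were BC018473 (4.38), Gimap4 (3.10) and Snora73b (2.46). Further genes among those farthest down were Ms4a7 (-4.11), Ccl3 (-3.96), Retnla (-3.91), the complement receptor gene C3ar1 (-3.73), the MHC class II gene H2-Aa (-3.68) and the chemokine gene Cxcl2 (-3.44). Of the 56 lower genes, 51 were at least 2-fold higher in wild-type LSK/Flt3+ than in wild-type LSK/Flt3- cells, a count that uses the same LSK/Flt3+ array on both sides, so part of it may come from that array. Only 12 of the 56 were also at least 2-fold below wild-type LSK/Flt3- cells on both null arrays. By size alone, 52 genes were at least 2-fold higher and 215 lower on both null arrays. Leaving out null replicate 1 gave 113 and 331, and leaving out replicate 2 gave 342 and 459. The count of lower genes was 17 with only genes of a mean level of at least 6, 101 after cyclic loess, 85 with arrays centred on their medians and 99 with robust estimation. Flt3 and Snora73b lost the call in some of these settings, with the adjusted p of Flt3 ranging from 0.00207 to 0.0838 and that of Snora73b from 0.00201 to 0.0605.

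By lists, macrophage and dendritic cell genes had the lowest median and fell in null against wild-type LSK/Flt3+ cells, with 17 of 18 members lower and a median of -1.19 (camera, adjusted p = 9.88e-39; adjusted p = 0.839 with an estimated correlation). Over all genes 6 of them passed, and 13 fell when adjusted over the list alone. Against wild-type LSK/Flt3- cells the median of the same list was -0.13. Lymphoid priming genes fell with 15 of 20 lower and a median of -0.42 (adjusted p = 7.03e-17; adjusted p = 0.839 with an estimated correlation), 4 over all genes and 8 adjusted over the list alone. B-lineage genes fell with 14 of 15 lower and a median of -0.40 (adjusted p = 8.08e-06; adjusted p = 0.839 with an estimated correlation), and the adaptor gene Blnk (-1.47) and Vpreb1 (-1.33) passed adjusted over the list alone. Their median was -0.27 on null replicate 1 and -0.44 on replicate 2. Immediate early and heat shock genes fell beside the macrophage genes, with 20 of 23 lower and a median of -1.06 (adjusted p = 2.82e-20; adjusted p = 0.839 with an estimated correlation). Hspa1a (-2.72) and the stress transcription factor gene Atf3 (-2.52) passed over all genes and 13 members adjusted over the list alone. Interferon response genes fell with 24 of 25 lower and a median of -0.44 (adjusted p = 5.28e-09; adjusted p = 0.839 with an estimated correlation), though 0 members passed limma over all genes or adjusted over the list alone, with 5 lower and 1 higher at an unadjusted p under 0.05.

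Stem cell (HSC) genes rose in null against wild-type LSK/Flt3+ cells, with 18 of 23 higher and a median of 0.41 (adjusted p = 4.69e-05; adjusted p = 0.839 with an estimated correlation). Slamf1 passed over all genes, and the von Willebrand factor gene Vwf was at 1.74 (1.15 on null replicate 1 and 2.33 on replicate 2). Megakaryocyte and platelet genes rose with a median of 0.65 and 14 of 17 higher (adjusted p = 5.65e-06; adjusted p = 0.839 with an estimated correlation), and the thrombin receptor gene F2r (1.55) passed adjusted over the list alone. The megakaryocyte median was 0.32 on null replicate 1 and 0.95 on replicate 2. The granulocyte-monocyte progenitor list rose with a median of 0.42 (adjusted p = 0.00292; adjusted p = 0.839 with an estimated correlation), with 5 members higher and 2 lower adjusted over the list alone. Its 2 lower members, Ly86 (-2.50) and the macrophage growth factor receptor gene Csf1r (-2.34), are also expressed by macrophages. Endothelial and stromal genes fell with a median of -0.15 (adjusted p = 0.000982; adjusted p = 0.839 with an estimated correlation), led by Emcn (-2.63, adjusted p = 0.0108), a marker of endothelium that stem cells also carry, and with only genes of a mean level of at least 6 the adjusted p was 0.864. The endothelial median was -0.05 on null replicate 1 and -0.26 on replicate 2 (percentiles 2.73 and 0.26). CDK inhibitor genes fell, with 6 of 6 lower and a median of -0.08 at percentile 15.0 of random lists (adjusted p = 0.000531; adjusted p = 0.839 with an estimated correlation), and Cdkn1b (-2.06) and Cdkn2c (-1.96) passed adjusted over the list alone, though Cdkn1b was at -1.17 with the mean of all its probe sets (adjusted p = 0.566 over all genes, from 0.00929 to 0.566 over the other settings). The median of the CDK inhibitor genes was -0.20 on null replicate 1 and -0.19 on replicate 2. Mitosis genes fell with a median of -0.14 (adjusted p = 0.00733; adjusted p = 0.989 with an estimated correlation), and the adjusted p was 0.0640 after cyclic loess. Their median was -0.27 on null replicate 1 and -0.08 on replicate 2. Circadian genes fell with a median of -0.20 (adjusted p = 0.00892; adjusted p = 0.988 with an estimated correlation), with Nfil3 at -1.48, and the adjusted p was 0.149 with only genes of a mean level of at least 6. The circadian median was -0.12 on null replicate 1 and -0.27 on replicate 2 (percentiles 3.65 and 0.21).

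DNA replication genes did not pass as a list against wild-type LSK/Flt3+ cells, with 34 of 56 higher, a median of 0.05 and adjusted p = 0.508, and 0 members passed limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05. Their median was 0.01 on null replicate 1 and 0.14 on replicate 2. Erythroid genes had a median of -0.03 (adjusted p = 0.778), with -0.23 on null replicate 1 and 0.22 on replicate 2. Mature neutrophil and monocyte genes had a median of 0.27, at percentile 99.8 of random lists, and a mean of -0.07 (adjusted p = 0.905), and the inflammatory cytokine gene Il1b fell (-2.60, adjusted p = 0.0147). With only genes of a mean level of at least 6, that list fell, with a median of -0.79 (adjusted p = 0.000214). With all its genes the neutrophil median was 0.01 on null replicate 1 and 0.27 on replicate 2, at percentiles 12.9 and 99.98. The mast cell list had a median of -0.17, at percentile 1.25, and a mean of 0.12 (adjusted p = 0.778), but on null replicate 2 the median was 0.05 at percentile 76.3, against -0.20 at 0.99 on replicate 1. Hox cluster genes (median 0.21) and sex-linked genes (-0.65) did not pass camera either, while their medians lay at percentiles 98.96 and 0.33. For the Hox list neither array alone lay outside the central 95%, with 0.26 on null replicate 1 and -0.01 on replicate 2 (percentiles 92.8 and 54.95). The sex-linked median was -0.29 and -1.02 (percentiles 15.6 and 0.03). In the p53 target list the kinase gene Plk2 fell (-2.27, adjusted p = 0.0194), with a list median of 0.08 (-0.01 on null replicate 1 and 0.12 on replicate 2) and a mean of -0.02 (adjusted p = 0.976).

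The third comparison, between the wild-type fractions, had 1 array on each side, so its differences have no replicate check and no p-value. Flt3 was higher by 0.89 on the log2 scale in LSK/Flt3+ than in LSK/Flt3- cells, and 184 genes were at least 2-fold higher and 35 at least 2-fold lower. Lymphoid priming genes were higher, with a median of 0.58 and 14 of 20 members up, including Dntt (1.81), the lymphocyte surface gene Cd52 (1.43), Il7r (1.38) and Jchain (1.17). Stem cell (HSC) genes were lower, with a median of -0.38 and 20 of 23 down, including the receptor gene Tek (-1.27), Slamf1 (-1.08) and Ctnnal1 (-0.82). Macrophage and dendritic cell genes were higher, with a median of 1.30 and 17 of 18 up, including Mrc1 (3.92), C1qc (3.29) and Adgre1 (2.96).

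Against 10000 random lists matched on expression, the medians of the macrophage, lymphoid priming, granulocyte-monocyte progenitor (0.39) and immediate early and heat shock (0.36) lists lay at percentile 100 in LSK/Flt3+ cells. Those of the stem cell and erythroid (-0.37) lists lay at percentile 0.00 and that of the megakaryocyte list (-0.23) at 0.10. Interferon response genes (0.24) lay at percentile 99.9, endothelial and stromal genes (0.23) at 99.1, mitosis genes (0.06) at 98.6, CDK inhibitor genes (0.32) at 98.5 and gate marker genes (0.23) at 98.2. DNA replication genes (-0.12, 39 of 56 lower) lay at percentile 2.20 and Hox cluster genes (-0.07) at 1.54. Genes farthest up with a mean level of at least 6 were C3ar1 (3.94), Ifi207 (3.48), Lilr4b (2.78), H2-Aa (2.73), Lilrb4a (2.56), Csf1r (2.35), Mpeg1 (2.30), Cd74 (2.18), Cybb (2.18) and H2-Ab1 (2.15). The calgranulin genes S100a8 (-2.07) and S100a9 (-1.36) and the folate carrier gene Slc19a1 (-1.38) were among the lowest. Slc19a1 was at -0.96 with the mean of all its probe sets. With only genes of a mean level of at least 6, which leaves few members in some lists, 7 list medians moved. The B-lineage median went from 0.21 to -0.01 (percentile 97.0 to 44.7), the T and NK cell median from 0.13 to -0.28, the imprinted one from -0.05 to -0.43 and the neuronal one from 0.05 to -0.75. The mature neutrophil and monocyte median went from 0.18 to 0.99, the mast cell median from 0.15 to 1.03 and the macrophage median from 1.30 to 1.87.

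**Figure D3:**
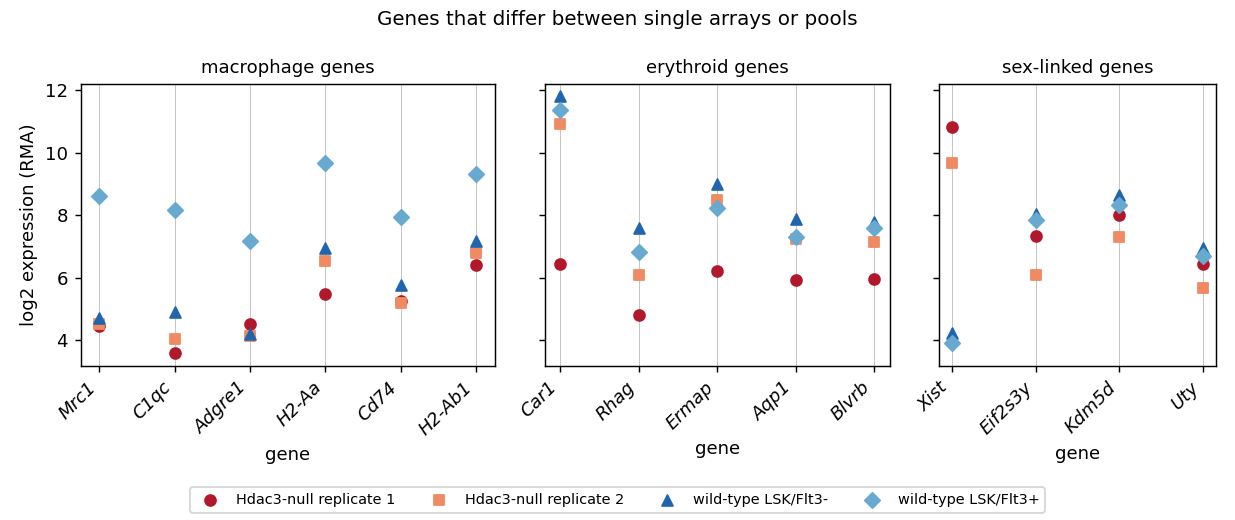
Log2 expression (RMA, y axis) of macrophage, erythroid and sex-linked genes (x axis) on each of the 4 arrays, with 1 point per array and no error bars. Macrophage genes stand apart in wild-type LSK/Flt3+ cells, Car1 is at 6.44 on null replicate 1 and 10.92 on replicate 2, and Xist is at 10.84 and 9.67 on the null arrays against 4.23 and 3.90 on the wild-type arrays.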

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

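The counts in this part were chosen after the deposited values were seen. Probe sets without a single named gene, 13767 in all, entered none of the comparisons. On both null arrays 178 of them were at least 2-fold higher than in wild-type LSK/Flt3- cells and 143 at least 2-fold lower. In wild-type LSK/Flt3+ cells 349 were at least 2-fold higher than in wild-type LSK/Flt3- cells and 579 lower. Null replicate 1 alone had 1792 such probe sets at least 2-fold higher than wild-type LSK/Flt3- cells and null replicate 2 had 344. The median level of these probe sets was 5.35 on null replicate 1, 4.87 on replicate 2, 4.96 in wild-type LSK/Flt3- and 4.97 in wild-type LSK/Flt3+ cells. No explanation of these signals was tested.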

How the results depend on the processing

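Quantile normalization was the one alternative chosen after the data were seen. No paired analysis was possible because the wild-type groups have 1 array each, and the planned run without shared-probe IDs (_x_at, _s_at) was not made since this array has none. Of the recomputed counts 80 stayed within 1.5 times and 38 did not; the cause of the moves was not tested except where named. Against wild-type LSK/Flt3- cells, the 4 higher genes became 2 with every probe set on its own, 2 with arrays centred on their medians, 0 with quantile normalization and 12 with a robust prior, and the 0 lower became 1 with every probe set, 1 with cyclic loess and 13 with a robust prior. Against wild-type LSK/Flt3+ cells, the 7 higher became 15 with a robust prior, and the 56 lower became 17 with a mean of at least 6 (fewer genes tested), 101 with cyclic loess, 85 with centring and 99 with a robust prior. Higher to lower split 4 to 0 against LSK/Flt3- and 7 to 56 against LSK/Flt3+ cells as deposited, 4 to 1 and 10 to 101 with cyclic loess, 2 to 0 and 10 to 85 with centring, and 0 to 0 and 6 to 71 with quantile normalization. With an estimated correlation, which could hardly pass any list here, the 11 and 12 lists past the threshold became 0 and 0. A mean of at least 6 left 50 genes 2-fold lower against LSK/Flt3-, 114 2-fold lower against LSK/Flt3+ and 66 higher between the wild types, and the excess of the null arrays' SD from LSK/Flt3+ over that from LSK/Flt3- cells, 0.0459 on average as deposited, became 0.0362, and 0.0554 with quantile normalization. Centring gave 57 genes lower between the wild types. By construction, a 1.5-fold limit gave 231 higher and 294 lower against LSK/Flt3-, 250 and 479 against LSK/Flt3+, and 698 and 335 between the wild types, and a 3-fold limit 14 and 19, 11 and 82, and 59 and 1. Without 1 null array, counts of genes 2-fold apart ranged from 133 to 267 higher and 165 to 240 lower against LSK/Flt3-, and from 113 to 342 and 331 to 459 against LSK/Flt3+, since 1 array is easier to meet than 2. The mature neutrophil and monocyte list against LSK/Flt3- reversed from 0.26 to -0.16 with a mean of at least 6 (adjusted p = 0.0171). Of the camera results 564 kept their side of the threshold with no called direction turned, 3 passed anew and 32 no longer passed, 23 of these with an estimated correlation. By percentile among random lists, with both null arrays or 1 of them, 143 list results kept the side that camera gave, 22 passed anew and 15 no longer did. Named genes with a test kept direction and side in 2181 cases, passed anew in 31 and no longer in 15. Signal over background was not given, so which dim genes were expressed is not known.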

Other observations

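The gene families and tests in this part were chosen after the values were seen, and 5 families were examined. Small nucleolar RNA genes of the Snora family stood apart on null replicate 1, with a median log2 difference of 1.19 from wild-type LSK/Flt3- cells and 20 of 20 genes higher. On replicate 2 the median was -0.14, with 8 of 20 higher, and the same signs held with cyclic loess, centring and quantile normalization. For 31 Snord genes the medians were 0.86 and 0.12, and with centring 0.66 and 0.09. For 8 Gimap genes, which encode lymphocyte GTPases, they were 0.39 and 0.27, and with centring 0.20 and 0.25. For 67 genes with symbols starting Rpl or Rps and a digit, the medians were -0.06 and 0.09, and with centring -0.25 and 0.07. This set was taken by symbol and is not limited to ribosomal protein genes. For 291 microRNA genes the medians were 0.33 and -0.003, but on replicate 1 only 0.11 with cyclic loess, 0.13 with centring and 0.12 with quantile normalization. The signs of the medians in these 4 families held under the 3 other scalings. Single genes with both null arrays apart included Gimap7 (8.34 and 7.71 against 6.45 in wild-type LSK/Flt3- cells), the cytokine receptor gene Csf2rb2 (7.58 and 7.47 against 5.87) and the MHC gene H2-T10 (8.41 and 8.47 against 7.04), none of them past the limma test over all genes (adjusted p = 0.729, 0.476 and 0.749).

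Macrophage genes led the wild-type LSK/Flt3+ array. RNA of macrophage-lineage cells in the sorted pool may account for this. Without the 3 genes named from the ranking, the macrophage and dendritic cell list still had a median of 0.85 and 14 of 15 members higher. Of these Mrc1, Cd68 and C1qc stood at 8.62, 8.54 and 8.18 against 4.70, 6.95 and 4.89 in wild-type LSK/Flt3- cells. Mrc1 and C1qc had already stood out in the comparison of null with wild-type LSK/Flt3+ cells, which uses the same array. The remaining members are therefore no independent check of the pattern. The T and NK cell and erythroid lists go against a larger share of every mature cell type alike. The higher of their upper quartiles was 0.22, and the lower quartile of the macrophage list without those 3 genes was 0.55. This is a limited check, since the T and NK cell list had a low median level (4.67) and the erythroid list is not limited to genes of mature cells. A rise of other myeloid lineages beside macrophages stays open: the upper quartile of the neutrophil and monocyte list was 0.47, and with only genes of a mean level of at least 6 its median was 0.99 and that of the mast cell list 1.03. The sort for lineage-negative cells may remove macrophages, but how far it did so was not checked. Of the macrophage list, 5 of 18 members had a level of at least 6 in wild-type LSK/Flt3- cells and 0 belonged to another list. Expression by Flt3+ progenitors themselves stays open and was not tested.

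Xist was far higher on both null arrays than on both wild-type arrays. A different sex makeup of the pooled mice may account for this, since the 3 measured Y-linked genes had a median difference of -1.0 from wild-type LSK/Flt3- cells. Xist raised with an equal sex makeup is argued against, since that median lay at percentile 0.05 of matched random lists. The random lists draw genes independently while Y-linked genes can vary together, so this percentile can be too extreme. A larger female share as the whole difference between the null pools is argued against too: replicate 1 had more Xist, by 1.17, but also higher Y-linked genes, with a median difference of 0.75, and 0.79 after cyclic loess. The SD of single-gene differences over all genes was 0.43, which is not the spread of a median of 3 genes. From wild-type LSK/Flt3- cells, Kdm5d was at -0.65 and -1.35 on replicates 1 and 2, Eif2s3y at -0.72 and -1.97 and Uty at -0.51 and -1.26. Sex makeup thus stays confounded with genotype for any sex-dependent gene, and a direct effect of Hdac3 on Xist beside it stays open.

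Erythroid genes were lower on null replicate 1 than on replicate 2, with Car1 apart by -4.49, Ermap by -2.25 and Gata1 by -1.66, and the narrower range of replicate 1 as a whole cause is argued against, since the list median was -0.40 after cyclic loess (percentile 0.01), as it was -0.38 before. Fewer erythroid cells with no other lineage apart was tested with 3 other lists, and 3 of 3 were also low after cyclic loess. They were the megakaryocyte (-0.36), mast cell (-0.50) and granulocyte-monocyte progenitor genes (-0.25). This cannot exclude the explanation, since whether the missing cells themselves express genes of these lists was not tested. These lists were already low as deposited (percentiles 0.37, 0.02 and 1.51), so cyclic loess adds little here. The granulocyte-monocyte progenitor list was the least clear, with an upper quartile of 0.12. RNA loss that hit every lineage alike cannot be told apart from a change in the cells: after cyclic loess the medians of the lymphoid priming (0.0791), stem cell (-0.01) and endothelial (0.13) lists go against it, but their lower quartiles (-0.19, -0.27 and -0.26) lie below the erythroid upper quartile of -0.17, and a first comparison, with the granulocyte-monocyte progenitor list, excluded nothing either. The lower quartiles of the B-lineage (-0.14) and T and NK cell (-0.08) lists lie above it, but these lists have low median levels (5.06 and 4.67), and although as deposited all 5 lists lay apart from the erythroid one (lower quartiles from -0.17 to 0.12 against an upper quartile of -0.23), this did not hold after cyclic loess for the lists of stem cell, lymphoid priming and endothelial genes. A difference in the makeup of these pools may remain. Beyond a lack of erythroid cells alone, no biological explanation was tested because both arrays carry the same label.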
